A study of Trachinotus blochii with 12 samples.

How the data were processed

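The series holds 12 RNA-seq libraries of golden pompano, 3 each from Tol liver, Intol liver, Tol brain and Intol brain, grouped by the status and tissue that the labels give. Per the labels' protocols, 14 fish of each status were taken from each of 3 tanks, 42 per status, after the oxygen had been lowered within 2 h. RNA with an integrity number above 8 was made into TruSeq libraries and sequenced as 125-bp paired ends on an Illumina HiSeq. Reads with adaptors, ambiguous bases or low quality were removed and the remaining reads were assembled with Trinity, per the labels' protocols. The labels do not say how many fish entered a library, or from which tank. The aligner, the counting tool, the genome build, the annotation and the normalization are not given in the sources used here.

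Each deposited file lists 1 value per gene model for 18490 gene models, with at most 2 decimals. The unit is named neither in the headers nor in the labels. The deposited values were read as FPKM (fragments scaled by gene length and library size), because they are not whole numbers and their sums differ between libraries, from 360680 to 622240, which CPM or TPM over these genes would not. If the unit is another, differences between libraries on the log2 scale keep their meaning only as far as the authors scaled libraries alike. The smallest value above 0 was 0.01. Steps of whole reads were searched in low-valued brain genes, but no bin of 0.02 in the log2 ratio between libraries held more than 6.56% of the genes, so no relative depth could be read and no counting interval is given. A value listed at 0 can be a failed estimate, and single values are given where a gene is listed at 0. The file of Intol brain replicate 2 held a further block of values headed as Intol brain replicate 1, all 18490 of which equal the values in that library's own file. This block was not used. No libraries were duplicates of each other, with at most 3.10% identical values in any pair.

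Each tissue was tested with limma 3.58.1 in R 4.3.3 on log2(value + 1), with values as deposited, a variance trend, robust moderation and group means as the only terms. Genes with a value of at least 1 in at least 3 of the libraries fitted were kept, and Benjamini-Hochberg adjusted p under 0.05 counted as a call. Changes are Tol minus Intol on the log2(value + 1) scale, which understates the change of low genes. The interaction, the liver change minus the brain change, was fitted over all 12 libraries with 4 group means. Overlaps were tested with Fisher's exact test, and measures per library with exact permutation tests, both two-sided. The steps were tested on simulated data with 100 genes changed by 1 and 100 by 2 on the log2 scale. The liver fit over 9109 genes recovered 71% and 98% of them with 3.43% false calls, the brain fit over 14146 genes 88% and 98% with 4.12%, and the interaction over 14817 genes 70% and 96% with 5.14%. The simulated noise was independent between genes, with rises and falls balanced and no shift between libraries. These shares therefore do not cover correlated genes or a shift of all genes. For the interaction, each gene was also simulated with the same spread in both tissues. In the data the median SE of a change was 0.157 in liver and 0.099 in brain. The interaction shares therefore do not cover genes whose spread differs between the tissues. Tables were handled with Python 3.11.15, NumPy 2.4.6 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.

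The tests, the alternatives and the rule for naming genes were chosen before the data were examined, except where the text says otherwise. The files pair no gene model with a gene name and no reference was given, so 0 gene models matched a member of the 48 gene lists (1243 members) set up for metabolism, hypoxia and cell types. The list tests, the check of tissue labels by marker genes and their alternatives were therefore not run, and the tissue labels were checked only by correlation between libraries. For the same reason the rule names at most 2 gene models that rose and 2 that fell per tissue. They are those with the largest changes among calls with a mean above the median of tested genes and 3 Tol values wholly above or below the 3 Intol values, a condition that 435 higher and 1350 lower calls met in liver and 1 and 2 in brain. Tissue classes, and their tests by camera and fry, were added after the data were seen.

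The alternatives tried were quantile normalization, median-ratio scaling, no filter or a mean of at least 5, limma without trend and robust options, pseudocounts of 0.1 and 5, the replicate number as a block, an absolute log2 change of at least 1, all 12 libraries in one fit, each library left out, and an unadjusted p under 0.01 for the overlap. Leaving out the 10 most abundant genes, class limits of 2 and 4, and the recalculation of the class counts and of the calls common to both tissues under the other alternatives were added after the data were seen.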

Results

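Golden pompano (Trachinotus blochii), a marine food fish, were held at a severe hypoxia of 0.9 mg/L dissolved oxygen, with a range of 0.1 mg/L, and mRNA was sequenced from liver and brain. The fish were 2 months old and were kept in 3 tanks of 80. The Intol fish were those that lost balance and were dying within 1 h of hypoxia, and the Tol fish were those still normal after 24 h. Each status was represented by 3 liver and 3 brain libraries, 12 in all, with values for 18490 gene models. Tol and Intol fish therefore also differed by 23 h of hypoxia and of fasting, and Intol fish were sampled while dying, so a difference between the groups belongs to status and time together. No library came from fish at normal oxygen. Rises and falls below therefore compare Tol with Intol fish, and do not say which group departed from a baseline. The comparison asked how the transcriptomes of tolerant and intolerant fish differ in each tissue. Its title names glucose and lipid metabolism, but the gene models were not paired with gene names in the sources used here, so genes of these pathways were not analysed here. Values were read as FPKM, and their sums per library ranged from 360680 to 622240. These sums are not read counts, and the sequencing depth is unknown. Nothing in the labels says whether each library came from 1 fish, so the p-values measure the spread between these samples.

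Liver and brain libraries formed separate types. Across genes, the correlation of log2 values was between 0.453 and 0.473 for the 36 pairs of a liver and a brain library. It was at least 0.981 within each liver group and at least 0.982 within each brain group. Tol and Intol livers correlated at 0.940 to 0.975, below the pairs within liver groups, and Tol and Intol brains at 0.983 to 0.991, inside the range within brain groups of 0.982 to 0.994. The low end of both brain ranges came from pairs with Intol replicate 3. Among brain pairs without that library, the correlation was 0.993 to 0.994 within groups and lower, 0.989 to 0.991, between Tol and Intol. In liver, the first principal component carried 71.9% of the variance and separated the groups, with scores from 27.0 to 39.4 in Tol and from -45.0 to -21.4 in Intol. In brain, the first component carried 38.6% and set Intol replicate 3 apart, at a score of -26.6 against -7.90 to 13.1 for the other libraries.

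**Figure D1:**
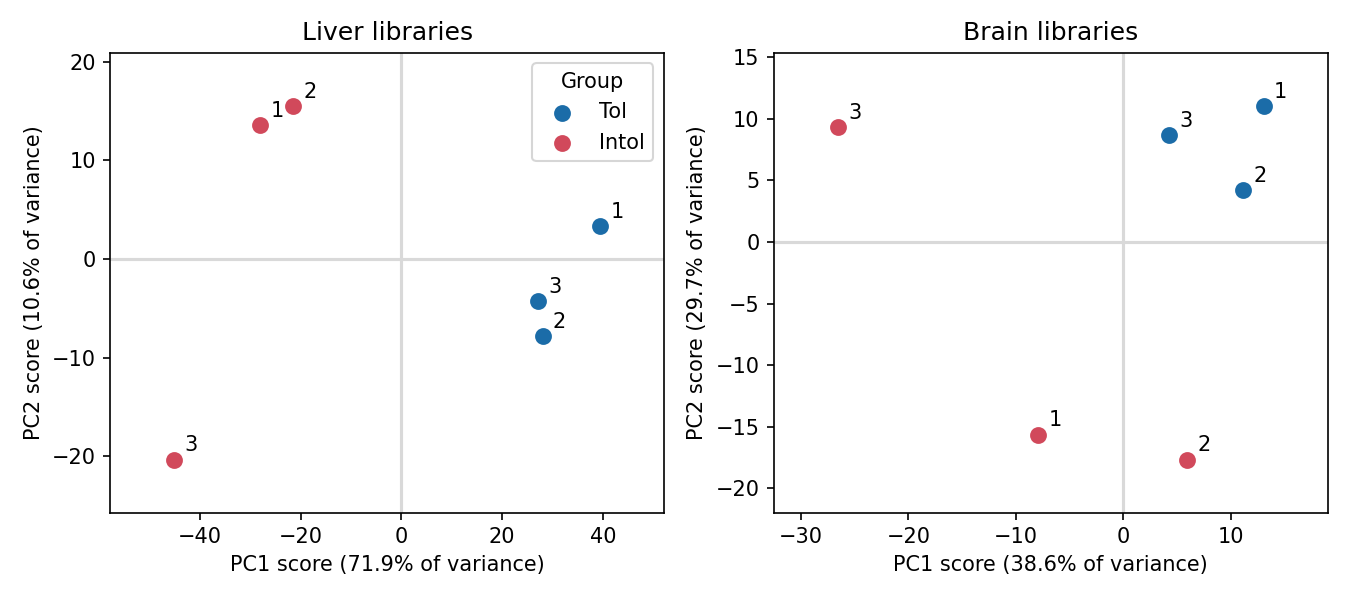
Principal component scores of the liver libraries (left) and brain libraries (right), from log2(value + 1), 1 point per library numbered by replicate, with the share of variance on each axis. Tol and Intol livers lie on opposite sides of the first component (71.9% of variance), while brain Intol replicate 3 stands alone at -26.6.

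Fewer genes reached a value of 1 in Tol than in Intol livers. The number was 8429 ± 164 in Tol and 9188 ± 170 in Intol (SD, n = 3), without overlap between the groups. The median value over all genes was 0.717 ± 0.050 in Tol and 0.977 ± 0.068 in Intol livers, and the 10 most abundant genes of each library held 27.2% ± 2.6 and 22.4% ± 1.1 of the summed values. Each of these differences had a two-sided exact permutation p of 0.1, the smallest that 3 against 3 libraries allow. The summed values themselves were 601096 ± 10312 in Tol and 605587 ± 21188 in Intol livers (exact permutation p = 0.7). In brain, 14070 ± 58 genes in Tol and 14017 ± 181 in Intol reached a value of 1 (exact permutation p = 0.8), and the 10 most abundant genes held 5.76% ± 0.06 and 5.73% ± 0.18 (exact permutation p = 1).

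The liver transcriptome differed widely between Tol and Intol fish, with most of the genes that passed the test lower in Tol. Of 9109 genes tested, 682 were higher and 2699 lower in Tol liver at a Benjamini-Hochberg adjusted p under 0.05 (limma), and the median size of these 3381 changes was 0.76 on the log2(value + 1) scale. Changes of at least 1 on that scale numbered 206 higher and 770 lower, and changes of at least 2 numbered 37 and 70. The 3 Tol values lay wholly above or below the 3 Intol values for 52.4% of the genes tested, against 10% by chance. An unadjusted p under 0.05 (limma) was found for 4349 genes, against 455 for independent unchanged genes. The 9 other splits of the libraries gave 53 to 380, but they mix Tol and Intol. A group difference then widens the spread within their groups and lowers these counts. The balance of directions depended on the scaling. The median change of all tested genes was -0.20 in the values as deposited and 0.03 after median-ratio scaling, where 1513 genes were higher and 1551 lower, so that 50.6% of calls were lower in place of 79.8%. All 682 higher calls and 1550 of the lower calls were made under both scalings with the same sign, 1149 lower calls were lost and 0 were called with the opposite sign. Without Intol liver replicate 1 the calls fell to 2234, with 1746 lower, and without Intol liver replicate 3 to 2214, with 430 higher and 1784 lower. The higher calls fell to 372 without Tol liver replicate 1 and to 385 without Tol liver replicate 2.

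**Figure D2:**
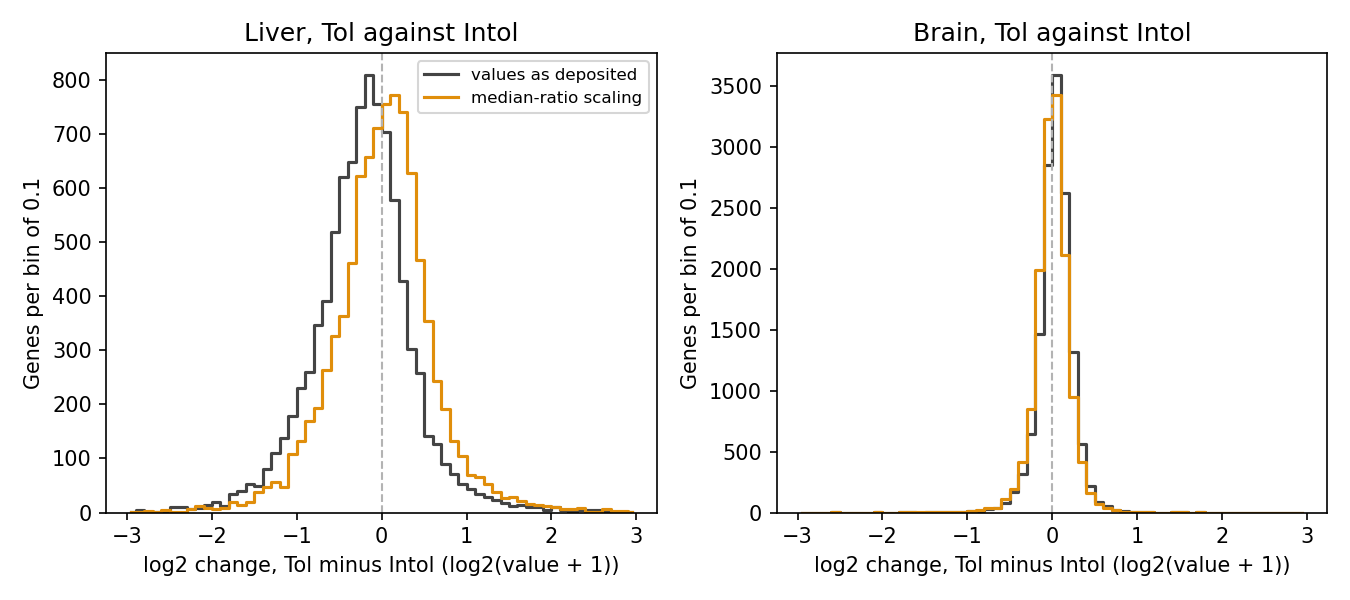
Number of genes by log2 change (Tol minus Intol, in bins of 0.1 on the log2(value + 1) scale) in liver (left) and brain (right), for the values as deposited and after median-ratio scaling. The liver distribution is broad, with its median at -0.20 as deposited and at 0.03 after scaling, while the brain medians are 0.04 and 0.00.

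**Figure D3:**
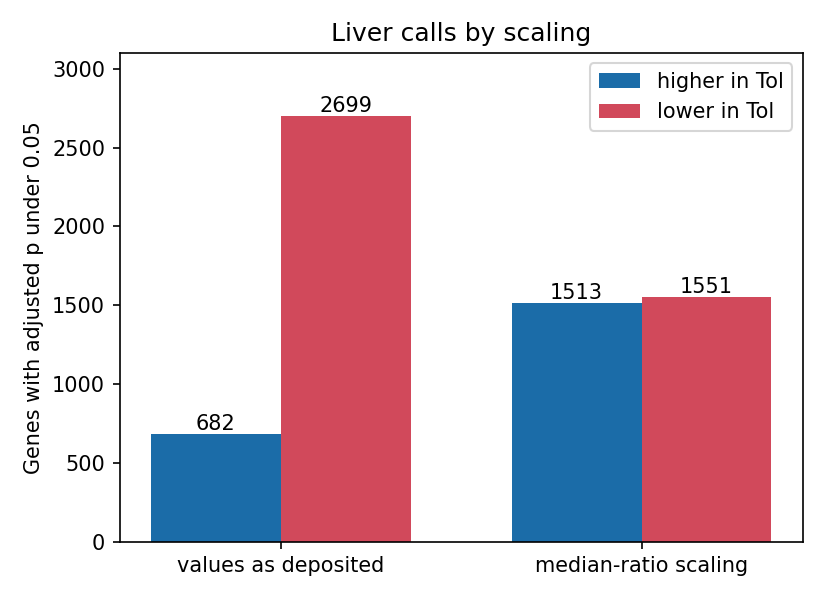
Number of liver genes with an adjusted p under 0.05 (limma), higher or lower in Tol, by scaling. Lower calls outnumber higher calls 2699 to 682 in the values as deposited, and the counts are 1551 and 1513 after median-ratio scaling.

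The gene with the largest rise in Tol liver that met the fixed rule was Trachinotus_GLEAN_10013991. Its values were 228.53, 716.75 and 102.57 in Tol and 0, 1.08 and 0 in Intol liver, a log2 change of 7.66 ± 0.73 (SE) with an adjusted p of 0.00115 (limma). The gene model numbered next to it, Trachinotus_GLEAN_10013992, had the largest fall. It was listed at 0 in all 3 Tol livers and at 366.65, 296.41 and 433.15 in Intol livers, with an adjusted p of 4.2e-08. Both models were at 0.33 or below in every brain library. Both changes are uncertain, because the sequences of these models were not used here and reads shared between them were not excluded. The sum of the models was 349 ± 324 in Tol and 366 ± 67.8 in Intol liver (SD, n = 3; exact permutation p = 0.7, where 0.1 is the smallest possible). Trachinotus_GLEAN_10009678 was higher in Tol liver, at 16.1 ± 3.8 against 0.637 ± 0.800 in Intol (SD, n = 3), with a log2 change of 3.47 ± 0.33 (SE) and an adjusted p of 0.000583. Trachinotus_GLEAN_10002135 was lower, at 0, 3.49 and 0 in Tol and 16.51, 34.37 and 33.24 in Intol liver, with a log2 change of -4.07 ± 0.66 (SE) and an adjusted p of 0.00583. It was listed at 0 in all 6 brain libraries.

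**Figure D4:**
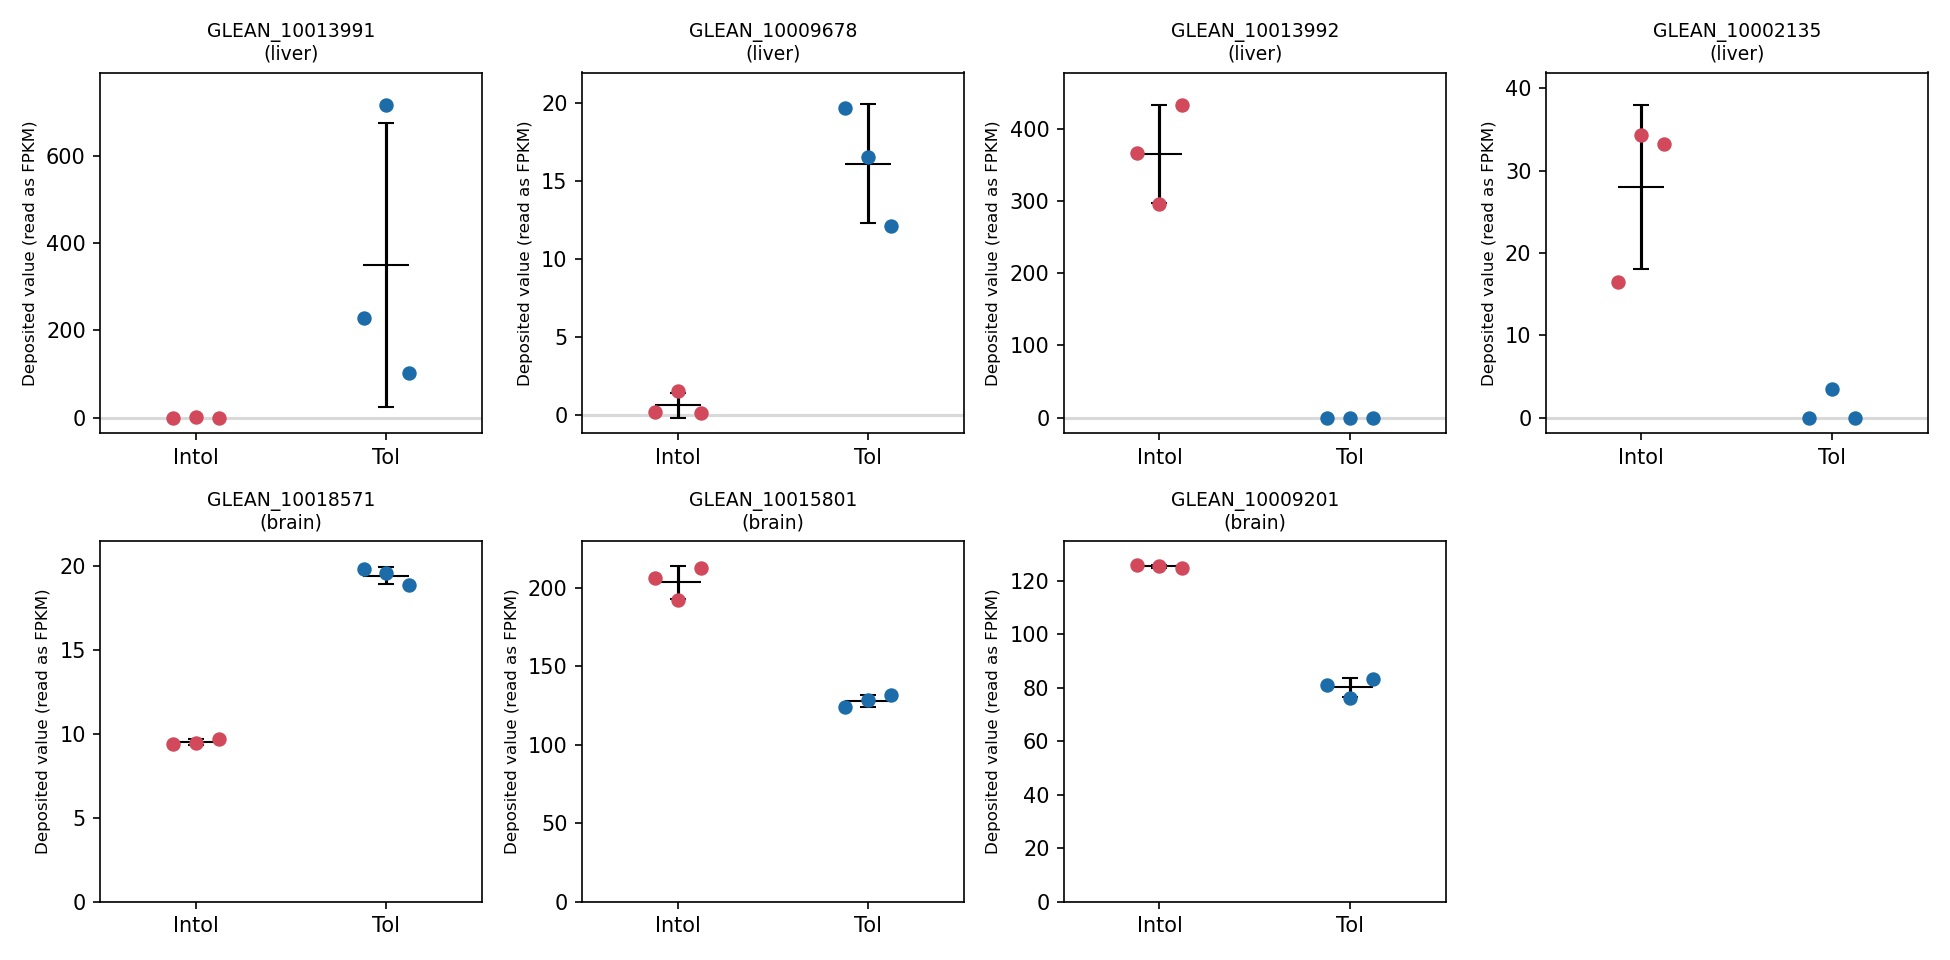
Deposited values, read as FPKM, of the 7 named gene models in the tissue where each was called, 1 point per library, Intol in red and Tol in blue. Bars show the mean and SD of 3 libraries and are left out where a library is listed at 0. Every Tol value lies outside the range of the Intol values of the same gene, which the rule for naming genes required.

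Genes were also counted by the tissue in which they were mainly expressed. With a class set, after the data were seen, as a mean difference of at least 3 on the log2 scale between the tissues, 73 of 474 liver-enriched genes were higher and 153 lower in Tol liver. Of 601 brain-enriched genes 27 were higher and 147 lower, and of 8034 genes in neither class 582 were higher and 2399 lower. The median changes of the classes were -0.18, -0.17 and -0.20, close to the median of all genes, and after median-ratio scaling they were 0.12, 0.04 and 0.03. The liver-enriched class then turned to 123 higher and 83 lower, and the brain-enriched class to 84 and 77. Under quantile normalization the counts were 102 higher and 114 lower for liver-enriched genes, and 93 and 74 for brain-enriched genes. Without Intol liver replicates 1 or 3 or Tol liver replicate 1 the brain-enriched genes lower in Tol fell to 73, 69 and 94. Genes in neither class that were lower fell to 1558 and 1590 without Intol liver replicates 1 or 3, and those higher to 294, 308 and 352 without Tol liver replicates 1 or 2 or Intol liver replicate 3. No class moved apart from the other genes by camera (limma) with a preset correlation of 0.01, with adjusted p of 0.179 for liver-enriched, 0.616 for brain-enriched and 0.320 for the other genes. With an estimated correlation the adjusted p were 0.498, 0.852 and 0.852. By fry (limma), which tests for a change in 1 direction without comparison to other genes, each class was lower in Tol in the values as deposited, with unadjusted p of 0.00599, 0.0126 and 0.00308.

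The brain differed far less by this test. Of 14146 genes, 1 was higher and 2 were lower in Tol brain at an adjusted p under 0.05 (limma). An unadjusted p under 0.05 (limma) was found for 2405 genes, against 707 for independent unchanged genes. The 9 other splits of the libraries, which also mix the groups, gave 169 to 1263. Trachinotus_GLEAN_10018571, a brain-enriched gene model, was 2.04-fold higher in Tol brain, at 19.5 ± 0.5 against 9.54 ± 0.17 (SD, n = 3), with a log2 change of 0.96 ± 0.06 (SE) and an adjusted p of 0.0055. Trachinotus_GLEAN_10015801 was lower, at 128 ± 3.7 in Tol against 204 ± 10.6 in Intol brain, with a log2 change of -0.66 ± 0.06 (SE). Trachinotus_GLEAN_10009201 was also lower, at 80.2 ± 3.5 against 125 ± 0.52, with a log2 change of -0.64 ± 0.06 (SE), and both had an adjusted p of 0.0194. The 3 Tol and 3 Intol values did not overlap for 22.7% of the genes tested, against 10% by chance. With each library left out, the changes stayed at 0.94 to 0.98 for Trachinotus_GLEAN_10018571, -0.71 to -0.63 for Trachinotus_GLEAN_10015801 and -0.67 to -0.60 for Trachinotus_GLEAN_10009201, but the number of calls moved. It fell to 0 without Tol brain replicate 1, Tol brain replicate 2 or Intol brain replicate 1, with 1296, 2061 and 1431 genes at an unadjusted p under 0.05 (limma), and to 1 without Intol brain replicate 3, while 11 were made without Tol brain replicate 3 and 25 without Intol brain replicate 2. With all 12 libraries in the fit, 110 genes were higher and 48 lower.

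The change between Tol and Intol differed between the tissues for 3540 of 14817 genes at an adjusted p under 0.05 (limma, interaction over the 12 libraries), and 5567 had an unadjusted p under 0.05. Only 8464 genes passed the filter in both tissues. For a gene near 0 in 1 tissue the interaction restates the change in the other. The fit took 1 spread per gene over both tissues, so a difference in spread between them was not modelled. The change in liver was larger in size for 3132 of the 3540 genes and the change in brain for 408, and 2533 were also liver calls. The change in liver lay below that in brain for 2998 and above it for 542, and after median-ratio scaling for 1500 and 1704. Trachinotus_GLEAN_10009201 was lower in Tol in both tissues and differed more in liver, at 10.1 ± 1.4 in Tol against 37.2 ± 12.5 in Intol (SD, n = 3), with an interaction of -1.09 ± 0.30 (SE) and an adjusted p of 0.0235. After median-ratio scaling within each tissue its changes were -1.44 in liver and -0.68 in brain. Its interaction under that scaling is not given here. Trachinotus_GLEAN_10015801 was also lower in Tol liver, at 35.8 ± 3.3 against 53.3 ± 10.5, with an adjusted p of 0.0448 that became 0.343 after median-ratio scaling. Its interaction of 0.12 ± 0.18 (SE) had an adjusted p of 0.680.

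Few calls were common to both tissues. Among 8464 genes tested in both, 2 of the 2 genes lower in Tol brain were among the 2493 lower in Tol liver, where 0.589 were expected from independent lists (two-sided Fisher's exact test, p = 0.0867). None of the 619 genes higher in Tol liver was called higher in brain, where 0 of these genes were called (limma). At an unadjusted p under 0.01 in each tissue, 22 genes were higher in Tol in both against 14.0 expected (odds ratio 1.65, 95% interval 1.00 to 2.60, Fisher's exact p = 0.035), and 45 were lower in both against 46.7 expected (odds ratio 0.95, 95% interval 0.661 to 1.34, Fisher's exact p = 0.864). Adjusted over these 4 overlap tests by Benjamini-Hochberg, the smallest Fisher's exact p became 0.14. At the unadjusted limit, 8 genes were higher in Tol liver and lower in Tol brain, and 48 were lower in Tol liver and higher in Tol brain. Across genes, which are not independent replicates, the changes in liver and brain correlated at r = 0.067 and rho = 0.055, and 48.4% had the same sign. Over the genes tested in each tissue the median change was -0.20 in liver and 0.04 in brain, and such opposite shifts lower the share of equal signs. Expected numbers for opposite directions and for equal signs were not calculated, so these values do not show disagreement between the tissues.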

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

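The tests of both patterns weighed here, and the counts of regroupings within liver and within brain, were chosen only after the results they bear on were seen, and the regroupings of the interaction were set up before.

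The Tol-against-Intol change differed between liver and brain for 3540 of 14817 genes, by the interaction test, while 8464 genes passed the filter in both tissues. Of 100 regroupings of Tol and Intol within each tissue, 1, the real one, gave as many, and the highest of the others gave 3291. That one kept the liver groups, as 7 of the drawn regroupings did, and no regrouping that mixed the liver groups gave more than 1 call. The count thus follows the liver groups, but mixing them puts their difference into the spread within groups and by itself lowers the count. For calls within a tissue the 10 possible splits are too few for a share under 0.05, and all but the real one mix the groups. In liver 1 split gave as many calls as the real 3381, with a highest other of 0, and in brain 1 split gave as many as the real 3, with a highest other of 1.

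The named gene models had been picked for a large change in 1 tissue, and all but Trachinotus_GLEAN_10015801 also passed the interaction test. The liver change minus the brain change on the log2 scale was 7.63 for Trachinotus_GLEAN_10013991, 3.03 for Trachinotus_GLEAN_10009678, -8.70 for Trachinotus_GLEAN_10013992 and -4.07 for Trachinotus_GLEAN_10002135. It was -1.17 for Trachinotus_GLEAN_10018571 and -1.09 for Trachinotus_GLEAN_10009201. Trachinotus_GLEAN_10013991, Trachinotus_GLEAN_10013992 and Trachinotus_GLEAN_10002135 were at 0.33 or below in brain and Trachinotus_GLEAN_10018571 at 0.35 or below in liver, so their values restate the change in 1 tissue and do not compare the tissues.

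The consecutively numbered Trachinotus_GLEAN_10013991 and Trachinotus_GLEAN_10013992 exchanged places in liver, each Tol library holding the first and each Intol library the second. Reads of near-identical or overlapping models given to one or the other are a candidate explanation, and a regulated switch between neighbouring genes is another. The log2 sum of the models differed by -0.49 between Tol and Intol against an SD within groups of 1.01, too wide a spread to decide. All 6 liver libraries had exactly 1 of the models above 50. The counting tool is not given, so how shared reads would be divided is unknown and this pattern does not separate the explanations. The sequences of the models, which were not used here, would be needed to separate them. Only these 2 of the liver gene models were listed at 0 in some library and at 50 or more in another, a limit set after the values were seen.

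The excess of lower calls in Tol liver, 2699 against 682, was weighed against depth and against a few abundant genes. Lower depth in Tol liver would leave abundant genes near 0, with a bound for depth set at a median above -0.05. A first test, on 581 genes with a mean log2 value of 6 or more, gave a median of -0.14, from -0.17 to -0.0976 with each library left out, which narrowly missed the bound of -0.10 set against depth. The 1173 genes from 4 to 6, looked at next and the band farthest from 0, gave -0.28, from -0.31 to -0.23, and the bands under 2 and from 2 to 4 gave -0.21 and -0.19. All 1754 genes of 4 or more, taken last, gave -0.20, from -0.23 to -0.15. They join the 2 bands from 4 up, whose medians had been seen, so a median at or below -0.10 was fixed in advance. This last test therefore decides nothing. In the first test, however, no median with a library left out came above -0.0976, and so none reached the -0.05 that depth would need. For these abundant genes the values argue against depth as the cause of the shift. For low genes depth stays open as a cause of the excess. Leaving out the 10 most abundant genes moved the median of all genes from -0.20 to -0.12, from -0.17 to -0.08 with each library left out, and leaving out 50, 100 or 200 moved it to -0.12, -0.10 and -0.07, on both sides of the bound of -0.10. With the 10 left out, 858 genes were higher and 2073 lower. A larger share for abundant genes in Tol liver therefore stays open, as does a true difference in many genes with status or time in hypoxia.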

How the results depend on the processing

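Leaving out the 10 most abundant genes, the class limits, and all alternatives for the class counts and for the calls common to both tissues except the unadjusted p were chosen only after the results were seen. Across the alternatives run, 0 liver, brain or interaction calls were called with the opposite sign. The filters, limma without trend and robust options, the block and the limit on size keep the fitted change and could not turn a sign. Nor could the fit of all 12 libraries. Under median-ratio scaling the fitted change of 2 liver and 31 interaction calls turned sign without passing the threshold. So did 2 interaction calls under quantile normalization, 2 with a pseudocount of 0.1 and 1 with a pseudocount of 5. Quantile normalization gave 1544 higher and 1556 lower liver calls, 8 brain calls (4 and 4), 1197 and 1354 interaction calls and 1 call lower in both tissues. Median-ratio scaling gave 1513 and 1551, 8 (4 and 4), 1704 and 1500, and 1. The mean filter of 5, which tests fewer genes, gave 1648 liver calls (413 higher, 1235 lower) and 12 brain calls (8 and 4). A log2 change of at least 1 left 976 liver calls (206 and 770), 1052 interaction calls (202 and 850), and 0 brain calls and 0 in both tissues, against 2405 brain genes at an unadjusted p under 0.05 (limma). With all 12 libraries fitted, 1042 liver genes were higher, 158 brain genes were called (110 and 48) and 7 were common. Plain limma, without trend and robust options, gave 1 brain call, with 0 lower and 0 common, and 2317 at an unadjusted p under 0.05. A pseudocount of 0.1 gave 5 brain calls (3 higher), no filter left 1 common call, and leaving out the 10 most abundant genes gave 858 higher and 2073 lower liver calls and 8 brain calls (4 and 4). An unadjusted p under 0.01 (limma) gave 67 common genes with the same direction, of 123 that passed in both tissues. Except for the filters and the limit on size, the cause was not tested.

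With each library left out, liver calls ranged from 2214 to 2918 (372 to 669 higher, 1746 to 2249 lower), brain calls from 0 to 25 (0 to 14, 0 to 11), interaction calls from 2507 to 3947 (354 to 683, 2137 to 3269) and common calls from 0 to 7. Brain genes at an unadjusted p under 0.05 (limma) then numbered 1296 to 2871. The liver gene models kept their calls in every alternative run, 13 for Trachinotus_GLEAN_10013992, which fails the filter without any Intol library, and 16 for the others. Their log2 changes depended on the pseudocount: with 0.1 and 5 they were 10.14 and 5.62 for Trachinotus_GLEAN_10013991, 5.00 and 1.90 for Trachinotus_GLEAN_10009678, -11.82 and -6.19 for Trachinotus_GLEAN_10013992 and -6.34 and -2.42 for Trachinotus_GLEAN_10002135. In brain, Trachinotus_GLEAN_10018571 kept its call in 13 of 16, Trachinotus_GLEAN_10015801 in 11 and Trachinotus_GLEAN_10009201 in 10. Depth is unknown, so its limit on low genes could not be set.

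Replicate numbers were not taken to pair the libraries. Deviations from group means correlated at 0.09, -0.12 and 0.07 between same-numbered Tol and Intol livers and at -0.07, 0.13 and 0.17 in brain. Between liver and brain of the same status and number they correlated at 0.03, 0.01 and 0.04 in Tol and 0.04, 0.09 and 0.11 in Intol. All were positive but mostly small, so a shared fish is not excluded. Of the pairs of different numbers, 8 of 12 were negative. This adds no evidence, because deviations sum to 0 within a group and positive pairs of the same number push the others below 0. The block gave 3513 liver calls, 15 brain calls (3 higher, 12 lower) and 6 common calls. For the interaction, a block within tissue gave 3189 calls and the fish number as a random effect 3802. The gene list alternatives were not run.

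Counts by tissue class in liver moved as well. Class limits of 2 and 4 gave 92 and 10 brain-enriched genes higher and 533 and 45 lower, and 105 and 51 liver-enriched genes higher and 225 and 104 lower. With all 12 libraries fitted, 104 liver-enriched genes were higher and 169 lower, 60 and 218 brain-enriched genes, and 878 and 3079 in neither class. The mean filter of 5 left 15 brain-enriched genes higher and 29 lower, and 324 and 1054 genes in neither class. Genes in neither class were 1349 higher and 1368 lower under quantile normalization, and 1306 and 1391 under median-ratio scaling. Without a filter 43 brain-enriched genes were higher and 201 lower, and with the 10 most abundant genes left out 41 and 103.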

Other observations

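All tests in this part were chosen only after the results they bear on were seen.

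Intol brain replicate 3, which stood apart on the first component, held 4 gene models at 50 or more that were below 1 in each of the other 5 brain libraries. Their values there were 518.11, 131.25, 66.55 and 58.64. No other brain library held such a gene model.

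Gene models abundant in liver were found at low levels in brain, and more so in Intol brain replicates 1 and 2. Over 74 of the 200 most abundant liver gene models, those below 1% of their liver level in every brain library, the median was 0.041% of the liver level in Intol replicate 1, 0.075% in replicate 2 and 0.018% in replicate 3, against 0.017%, 0.019% and 0.027% in the Tol brains. The median of 1 Intol brain lay at or below the highest Tol brain, which decides nothing about a rise with intolerance or early hypoxia, so that stays open. Liver RNA carried into those libraries may be the source, and would add 1 share of the liver level to every gene. That share was taken as the excess of Intol replicate 2 over Intol replicate 3, the library that stood apart on the first component. The upper quartile of this excess was 2.58 times the lower, between the bounds of 2 and 3 that were set, so this stays open too. The ratio depended on how many genes were taken, at 1.60 for the 50 and 1.82 for the 100 most abundant.

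Genes with consecutive numbers were examined for a common change in liver, as a hypothesis raised by the pair of neighbouring models. The Spearman correlation across 4562 pairs of consecutive models, which are not independent replicates, was 0.135, above the highest of 1000 shuffles at 0.047, and it was 0.013 at a distance of 2. In brain it was 0.066 over 10263 pairs. This is consistent with neighbouring or split models changing together, which the sources used here cannot separate.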
